A study of Homo sapiens with 24 samples.

How the data were processed

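RNA from OVCAR8 cells, a human line of high grade serous ovarian cancer, was sequenced by the authors in 24 libraries, 3 for each of 8 groups. The cells had been kept in ultra-low attachment plates, in conditioned medium mixed 1 to 1 with RPMI medium containing 5% serum. Per the labels, RNA was taken with Trizol and a column with a DNase step, and polyA libraries were made with the NEBNext Ultra 2 kit. The submitters' notes name STAR 2.6.1, DESeq2 (version given as 2) and the human genome build GRCh38, without saying what each was used for. The read counter and the strand of the libraries are not given in the sources used here.

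The deposited table holds raw read counts per gene and, per the file headers, FPKM values of the same libraries for 58735 genes. The FPKM deposited by the authors are counts divided by the gene length in the table, in kilobases, and by an effective library size. Dividing the counts by gene length and by 1 constant per library gave back the FPKM within a relative tolerance of 1e-04, and these constants were 0.965 to 1.04 times the library totals. Total counts per library ran from 14718120 to 21956598, and mitochondrially encoded genes took 4.09% to 6.85% of them. Pairs of replicates differed by more than counting noise, so none was a copy of another. Gene positions and types, and the GC content of 99.96% of the genes, came from GENCODE release 29 and the GRCh38 sequence, as did the lengths of coding transcripts (median per gene) used for the ribosomal protein list.

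Choices of comparisons, tests, gene lists, named genes and other settings to try were made before the data were examined. The plan was written for FPKM (limma on log2 values) with a clause that counts, if present, would be tested with edgeR, and that clause was followed. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood negative binomial models, TMM factors of 0.957 to 1.03), with 1 mean per group over all 24 libraries and 16 residual degrees of freedom. Robust estimation of the dispersion was used, which the clause did not mention. The filterByExpr function kept 19210 genes, and the common biological coefficient of variation was 0.0638. Two-sided p values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Sensitivity was tested on simulated data written after a first look at the fits. These data gave every group the same dispersion per gene. Recovery under the larger spread within the pre-treated than the direct groups was thus not tested. The simulated data held no GC or length trends, and the changed genes had at least 50 counts on average, so recovery of weaker genes was not tested. Of such genes changed by 1.25, 1.5 and 2 times, 44.8%, 73.1% and 97% were recovered for senescent against proliferative medium, 47.8%, 85.1% and 95.5% for the pre-treated pair, and 41.8%, 83.6% and 95.5% for the small fraction against senescent medium. Unchanged genes were 12 of 170, 11 of 175 and 10 of 168 calls in the same order, and 0 of 30 unchanged lists were called in each. Those lists were random genes simulated independently, so they do not bear on lists whose members vary together.

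The comparisons were proliferative against fresh medium, senescent against proliferative medium, the same pair after pre-treatment and the difference between these effects (an interaction contrast), each preparation of senescent medium against proliferative and against intact senescent medium, and the fractions against each other. The labels name the replicates by number without saying that equal numbers belong together, so no pairing was assumed. The response shared between comparisons was described by the correlation and covariance of log2 fold changes across genes, beside the covariance that shared libraries alone gave in 20 simulations. The named genes are the 12 largest rises and 12 largest falls for senescent against proliferative, proliferative against fresh, the pre-treated pair and the preparations against intact senescent medium, and the 5 largest each way for the rest, among genes with symbols past the threshold with a mean FPKM of at least 1 in a group. For the interaction they are the 5 smallest p values, and for each list up to 4 members with the largest changes; a gene named in one comparison could be cited in another. From these the text mainly takes genes whose call held with any 1 library left out, and it favours protein-coding genes, and both preferences were set after the values were seen. Levels are CPM, counts scaled to a common depth with TMM factors, and log2 CPM used a prior count of 2.

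Each of 37 gene lists, with 760 of 761 members found in the table, was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison, and repeated with an estimated correlation. Lists with under 5 measured members were described only. Members were also counted with p values adjusted over the list alone. The lists began with inflammatory cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation, mitosis, DNA replication, hypoxia targets and glycolysis. For lipids and stress they were cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, fatty acid oxidation and PPAR targets, the ATF4 amino acid response, the unfolded protein response, heat shock proteins, p53 targets, NRF2 targets, metallothioneins and metal response, and AhR targets. For cell identity and signals they were stem-like cell markers, epithelial genes, mesenchymal genes, TGF-beta targets, YAP targets, extracellular matrix and integrins, and immediate early genes. The rest were nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, purine and pyrimidine synthesis, autophagy and lysosome, senescence-associated genes, leukocytes, fibroblasts and endothelium as other cells, and replication-dependent histones and nuclear and non-coding RNAs for RNA quality.

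Other settings chosen in advance were limma on log2 FPKM with a pseudocount of 0.1, on FPKM as deposited and after quantile normalization, no filter on low counts, only genes with a mean FPKM of at least 5, only the libraries compared, a block for the replicate number, each library left out in turn, an estimated correlation between list members, and DESeq2 1.42.0. Settings added after the data were seen were DESeq2 size factors in edgeR, library totals without TMM, no robust dispersion, limma on scaled FPKM with a pseudocount of 1, a correction of each library for GC content and gene length, and a fit without 4 libraries (proliferative pre-treatment 1, senescent 3, senescent pre-treatment 3 and small fraction 1). Boiled or fractionated proliferative or fresh medium was not analysed here, and neither was any other assay. Some genes that the rule names are not reported here.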

Results

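RNA was measured by polyA sequencing in OVCAR8 cells, a line of high grade serous ovarian cancer, held in ultra-low attachment plates, whose surface keeps cells from adhering. The 24 libraries fell into 8 groups of 3. In 3 groups the cells received fresh medium, medium conditioned by vehicle-treated proliferating cells (proliferative medium), or medium conditioned by cells made senescent with cisplatin (senescent medium). Another 3 groups received senescent medium that had been boiled, its fraction below 3 kDa (small fraction) or its fraction above 3 kDa (large fraction). The last 2 groups were pre-treated with proliferative or senescent medium, and the labels do not say what followed. Conditioned medium was mixed 1 to 1 with fresh medium containing 5% serum. Total counts per library ran from 14718120 to 21956598. Values after a gene name are log2 fold changes ± standard error (SE) with 3 libraries per group. They come from edgeR quasi-likelihood fits with Benjamini-Hochberg adjustment over 19210 genes. Every SE was derived as the absolute log2 fold change divided by the square root of the F statistic of its test. It is not a fitted standard error, and it is approximate, above all for genes with few counts. Rose or fell is written of genes past an adjusted p of 0.05. Levels are means of depth-scaled counts (CPM) ± SD of 3 libraries. The labels do not say that replicates came from separate cultures, so these p values measure a spread between samples that may be technical. Coordinates are on GRCh38.

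The first comparison asked what medium from proliferating cells did beside fresh medium. The hypoxia gene CA9, a carbonic anhydrase (ENSG00000107159, chromosome 9, 35673856 to 35681159), rose from 0.135 ± 0.18 CPM in fresh medium to 2.83 ± 0.429 in proliferative medium (4.29 ± 0.53, edgeR adjusted p = 7.81e-09). NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022), also induced by low oxygen, rose from 168 ± 7.54 to 1706 ± 25.2 CPM (3.35 ± 0.04, edgeR adjusted p = 1.44e-44). Other large rises were the keratins KRT16 (3.76 ± 0.29) and KRT17 (3.37 ± 0.10), the protease inhibitor SLPI (3.51 ± 0.16) and the secreted hormone STC1 (3.25 ± 0.10). The growth factor receptor subunit GFRA1 (-2.12 ± 0.15), the semaphorin SEMA3D (-1.77 ± 0.21) and the kinase SGK1 (-1.61 ± 0.11) fell. In this comparison 3966 genes rose and 4138 fell.

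Among lists of genes chosen beforehand, 22 of 24 measured hypoxia targets rose and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 5.09e-109), ANGPTL4 (2.53 ± 0.13) and BNIP3 (2.13 ± 0.05) among them. For glycolysis genes such as HK2 (2.21 ± 0.07) and PGK1 (1.75 ± 0.03), 16 of 19 measured genes rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 3.73e-52). Metal handling moved the same way, as 6 of 6 measured metallothionein and metal response genes rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 1.14e-10), including MT1X (2.82 ± 0.21). Antiviral response genes were higher: 21 of 29 measured interferon-stimulated genes rose and 1 fell (22 and 2 adjusted over the list alone, camera adjusted p = 2.34e-21), with OAS2 (4.19 ± 0.54) and IFIT2 (2.31 ± 0.09) showing large rises. Cytokine and NF-kB genes such as LIF (1.16 ± 0.14) and RELB (1.06 ± 0.16) followed, and 15 of 23 measured inflammatory cytokines and NF-kB targets rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.000121).

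Genes of cell division were lower in proliferative than in fresh medium. Of the mitosis list, 0 of 33 measured genes rose and 31 fell (0 and 32 adjusted over the list alone, camera adjusted p = 3.16e-21), with NUSAP1 (-0.81 ± 0.14) and CENPE (-0.77 ± 0.08) as examples. Of the DNA replication list, 0 of 35 measured genes rose and 35 fell (0 and 35 adjusted over the list alone, camera adjusted p = 2.28e-26), and CLSPN (-1.42 ± 0.10) and CCNE2 (-1.21 ± 0.13) fell furthest. Sterol genes fell as well, since 1 of 24 measured cholesterol synthesis and uptake genes rose and 16 fell (1 and 17 adjusted over the list alone, camera adjusted p = 3.5e-09), INSIG1 (-1.26 ± 0.08) among them. In lipid synthesis 1 of 13 measured fatty acid synthesis genes rose and 10 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.81e-07). The chaperones HSPA1B (-1.25 ± 0.07) and HSPH1 (-0.98 ± 0.05) were part of a list in which 1 of 17 measured heat shock proteins rose and 15 fell (1 and 15 adjusted over the list alone, camera adjusted p = 4.32e-17). Ribosome assembly behaved alike: 1 of 23 measured ribosome biogenesis and MYC targets rose and 17 fell (1 and 18 adjusted over the list alone, camera adjusted p = 2.62e-07), and the polyamine enzyme ODC1 (-1.09 ± 0.07) fell. Finally 0 of 13 measured mitochondrially encoded genes rose and 11 fell (0 and 12 adjusted over the list alone, camera adjusted p = 3.23e-12). Beside them 6 of 34 measured nuclear oxidative phosphorylation genes rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.828, with a median log2 fold change of 0.04, a mean of 0.02 and a test direction of lower).

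**Figure D1:**
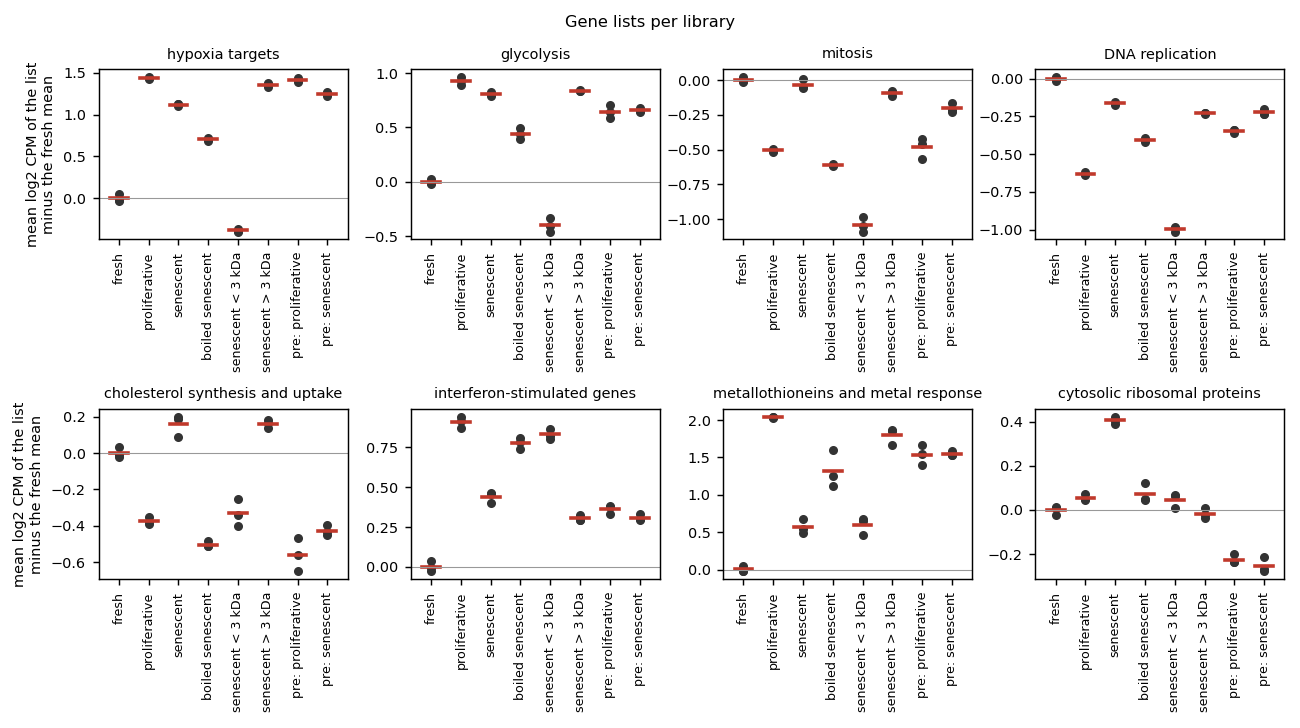
Mean log2 CPM of the measured members of 8 gene lists, minus the mean of the 3 fresh libraries, for each library (points) with group means (bars) in the 8 groups. Hypoxia targets and metallothioneins lay above 0 in every proliferative library, and hypoxia targets lay below 0 in every library of the small fraction (below 3 kDa).

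The main comparison asked how medium from cisplatin-induced senescent cells differed in effect from proliferative medium. The collagenase MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160), a common component of the senescence-associated secretory phenotype, stood at 16.3 ± 1.66 CPM in fresh, 9.79 ± 0.576 in proliferative and 42.9 ± 3.73 in senescent medium (2.13 ± 0.10, edgeR adjusted p = 5.46e-20). The sterol sensor INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235) stood at 42 ± 1.62, 17.6 ± 0.507 and 39.1 ± 1.22 CPM in the same order of media (1.15 ± 0.08, edgeR adjusted p = 2.01e-14). The metallothionein MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) fell from 39.6 ± 2.53 in proliferative to 8.2 ± 1.57 CPM in senescent medium, beside 5.57 ± 0.433 in fresh medium (-2.27 ± 0.20, edgeR adjusted p = 2.47e-08). The interferon-stimulated gene IFIT2 (ENSG00000119922, chromosome 10, 89283694 to 89309276) fell from 55.2 ± 1.37 to 18 ± 0.925 CPM, with 11.1 ± 0.583 in fresh medium (-1.62 ± 0.09, edgeR adjusted p = 9.02e-19).

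Senescent medium was not tested against fresh medium, so rises and falls here are relative to proliferative medium. Between senescent and proliferative medium 3186 genes rose and 2389 fell, or 2198 and 3558 with library totals in place of trimmed-mean (TMM) factors. A log2 change above 1 was reached by 83 of the rises and 305 of the falls. Of the 12 largest rises among named genes, 4 were protein-coding, the others being pseudogenes, small or non-coding RNAs. The protein-coding ones included KRT34 (2.26 ± 0.40) and VSTM1 (1.52 ± 0.44), and further down the ranking the neurotrophic co-receptor GFRA1 (1.31 ± 0.16) and the oxidase AOX1 (1.23 ± 0.16). Large falls included MT1M (-2.01 ± 0.26), the prostaglandin synthase PTGDS (-1.92 ± 0.25) and the complement gene C4A (-1.35 ± 0.34), which has a near-identical copy and is uncertain for that reason.

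Cell division genes were higher in senescent medium: 31 of 33 measured mitosis genes rose and 0 fell (32 and 0 adjusted over the list alone, camera adjusted p = 1.55e-33), with HMMR (0.70 ± 0.07) and TTK (0.65 ± 0.07) in front. For DNA replication, 35 of 35 measured genes rose and 0 fell (35 and 0 adjusted over the list alone, camera adjusted p = 2.18e-26), including CLSPN (1.00 ± 0.10) and MCM10 (0.78 ± 0.11). In the sterol pathway 20 of 24 measured cholesterol synthesis and uptake genes rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 3.45e-27), such as IDI1 (1.07 ± 0.06). The lipid enzymes FADS1 (0.70 ± 0.05) and FASN (0.60 ± 0.04) belonged to a list where 11 of 13 measured fatty acid synthesis genes rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.02e-14). Nucleotide synthesis moved likewise, with CTPS1 (0.80 ± 0.06), and 12 of 16 measured purine and pyrimidine synthesis genes rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.2e-09). Chaperone genes rose too, HSP90AA1 (0.73 ± 0.04) for example, as 15 of 17 measured heat shock proteins rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 6.18e-15). Of the endoplasmic reticulum stress genes, 8 of 19 measured unfolded protein response genes rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000741), among them SDF2L1 (0.58 ± 0.11). That call was lost with genes of mean FPKM of at least 5 (adjusted p = 0.112) and with quantile normalization (adjusted p = 0.145).

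Genes for translation rose. 34 of 40 measured cytosolic ribosomal proteins rose and 0 fell (34 and 0 adjusted over the list alone, camera adjusted p = 2.19e-32), RPL9 (0.67 ± 0.08) and RPS7 (0.62 ± 0.04) among them, and the list's median log2 fold change was 0.36. Copies of these short transcripts resemble one another and their pseudogenes, so single members are uncertain. In ribosome assembly 19 of 23 measured ribosome biogenesis and MYC targets rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 1.52e-14), with ODC1 (0.79 ± 0.07) and SRM (0.63 ± 0.07). Respiratory chain genes encoded in the nucleus moved the same way: 19 of 34 measured nuclear oxidative phosphorylation genes rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 3.39e-07), with ATP5PO (0.56 ± 0.10). By contrast 3 of 13 measured mitochondrially encoded genes rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.593). Short genes were favoured in the senescent libraries, whose deviations from the mean of all libraries correlated with gene length by r = -0.38, -0.38 and -0.26 across 10861 genes, which are not independent replicates. The largest axis of spread within groups, 30.1% of the residual variance of those genes, followed GC content (r = -0.64 across genes).

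Hypoxia genes were lower in senescent than in proliferative medium, as 0 of 24 measured hypoxia targets rose and 17 fell (0 and 18 adjusted over the list alone, camera adjusted p = 1.4e-14), VEGFA (-0.76 ± 0.08) and PDK1 (-0.54 ± 0.07) among them. The hypoxia target NDRG1 lay at 1239 to 1293 CPM in the senescent libraries, below 1677 to 1724 in proliferative and above 159 to 174 in fresh ones. Antiviral genes were lower too: 0 of 29 measured interferon-stimulated genes rose and 18 fell (1 and 19 adjusted over the list alone, camera adjusted p = 6.18e-15), with OAS2 (-1.68 ± 0.41) and OASL (-1.32 ± 0.10). Among metal response genes, 0 of 6 measured members rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 4.83e-13), including MT1E (-1.67 ± 0.11). Glycolysis was split, since 2 of 19 measured glycolysis genes rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.231 with an estimated correlation), and the call was lost with a GC and length correction (adjusted p = 0.0833). HK2 (-0.58 ± 0.07) and ENO2 (-0.50 ± 0.07) fell. Immediate early genes, which answer growth signals within minutes, were mostly higher: 13 of 24 measured immediate early genes rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 7.32e-06), with DUSP1 (0.88 ± 0.06) and KLF2 (0.63 ± 0.11).

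Genes tied to senescence included MMP1 and PLAUR (0.53 ± 0.06), and 7 of 15 measured senescence-associated genes rose and 0 fell (7 and 2 adjusted over the list alone, camera adjusted p = 6.18e-05). Among the rises was LMNB1 (0.37 ± 0.05), which senescent cells themselves lose, so its rise is not a sign of senescence. The call of the list was lost with quantile normalization (adjusted p = 0.502). YAP, a sensor of attachment and stiffness, was represented by ANKRD1 (0.64 ± 0.07) and CYR61 (0.64 ± 0.04), and 9 of 16 measured YAP targets rose and 0 fell (9 and 1 adjusted over the list alone, camera adjusted p = 9.47e-06), lost with quantile normalization (adjusted p = 0.155). In the amino acid response, PSAT1 (1.02 ± 0.08) and SLC7A11 (0.94 ± 0.14) rose and NUPR1 (-1.32 ± 0.33) fell. There 18 of 33 measured ATF4 amino acid response genes rose and 4 fell (18 and 4 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.0905 with an estimated correlation), lost also with genes of mean FPKM of at least 5 (adjusted p = 0.106) and with quantile normalization (adjusted p = 0.0684). The matrix list was mixed, with ITGB4 (-1.16 ± 0.04) and COL5A1 (-0.92 ± 0.20) lower and COL12A1 (1.00 ± 0.05) and LAMB3 (0.94 ± 0.09) higher, and 5 of 26 measured extracellular matrix and integrin genes rose and 11 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.118 with an estimated correlation). That call was also lost without proliferative library 2 (adjusted p = 0.0539), with no filter on low counts (adjusted p = 0.0785) and in limma fits of FPKM (adjusted p = 0.0793 to 0.0815). With a GC and length correction the list's mean log2 fold change was 0.03 rather than -0.08 (adjusted p = 0.896).

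Several lists were not called as a whole, though members of some of them rose and others fell. Of the secreted signals, 5 of 23 measured inflammatory cytokines and NF-kB targets rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.288). For the surface display of peptides, 2 of 15 measured antigen presentation genes rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.341). In stress pathways, 4 of 23 measured p53 targets rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.538). For antioxidant genes 8 of 22 measured NRF2 targets rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.067), TXN (0.68 ± 0.06) and GCLM (0.45 ± 0.06) rising and the transporter ABCC3 (-1.35 ± 0.13) falling. Lipid sensing gave similar results: 0 of 8 measured LXR targets rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.176). Likewise 1 of 14 measured fatty acid oxidation and PPAR targets rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.288). For the aryl hydrocarbon receptor (AhR), 1 of 8 measured AhR targets rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.163), with AHRR (-0.89 ± 0.11) and CYP1B1 (-0.68 ± 0.08) falling. Lysosomal genes went both ways, as 8 of 23 measured autophagy and lysosome genes rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.758, with a median log2 fold change of 0.01, a mean of -0.03 and a test direction of lower).

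Genes of cell identity were also mixed. 2 of 16 measured stem-like cell markers rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.934), KLF4 (-0.75 ± 0.11) falling and MYC (0.41 ± 0.05) rising. In the epithelial set, 4 of 14 measured genes rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.221). In the mesenchymal set 2 of 16 measured genes rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.403), with FN1 (-0.54 ± 0.03) lower. The secreted adhesion protein TGFBI (-1.12 ± 0.03) fell although 4 of 18 measured TGF-beta targets rose and 5 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.163). Markers of other cells gave no call, since 0 of 4 measured leukocyte markers rose and 0 fell (0 and 0 adjusted over the list alone), too few for a test. Next 0 of 6 measured fibroblast markers rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.128), and 0 of 5 measured endothelial markers rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.621). For RNA quality, 0 of 14 measured replication-dependent histone genes rose and 3 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0575). Further 2 of 5 measured nuclear and non-coding RNAs rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.0575, with a median log2 fold change of -0.10, a mean of 0.08 and a test direction of lower), NEAT1 (-1.30 ± 0.09) falling.

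**Figure D2:**
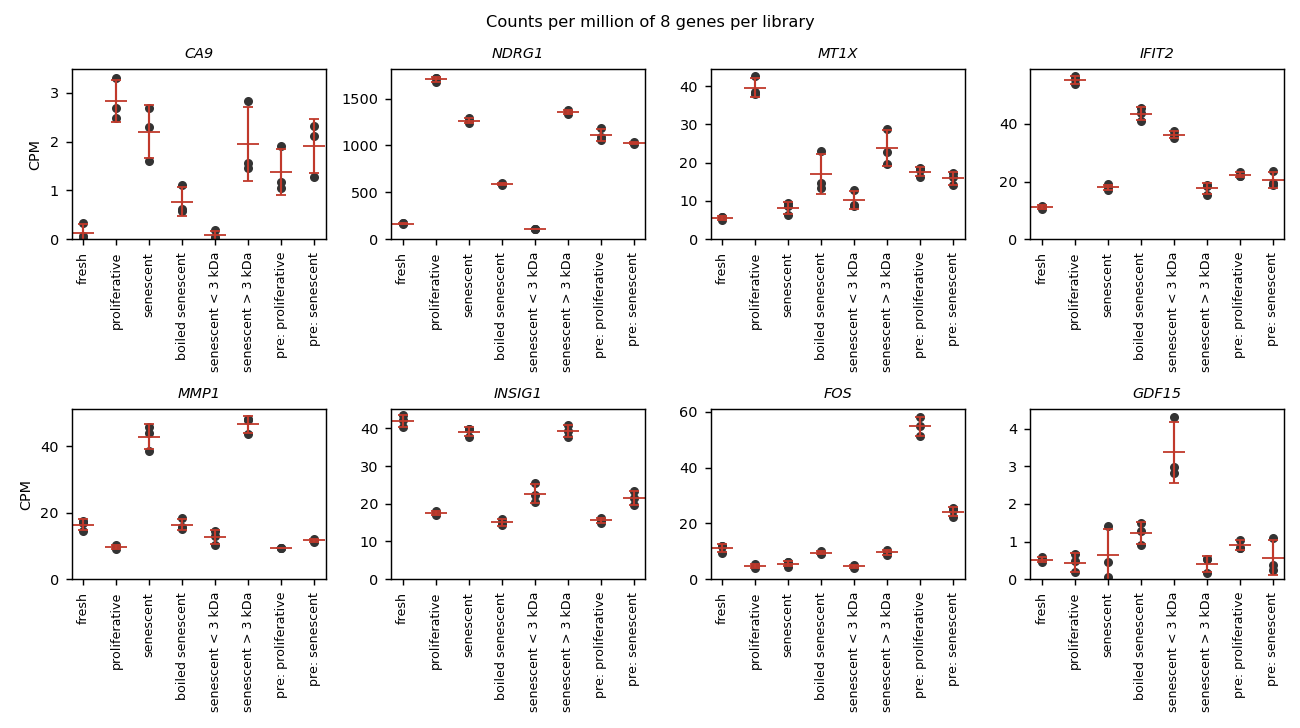
CPM on a linear axis of 8 genes in each library (points) with the mean and SD of 3 libraries (bars), by group. MMP1 lay between 38.7 and 45.8 CPM in the senescent libraries and between 9.14 and 10.2 in the proliferative ones.

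The same pair of media was compared in pre-treated cells, which asks whether an effect was seen after pre-treatment. Far fewer genes passed, 120 higher and 51 lower. The immediate early gene FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) stood at 54.8 ± 3.42 CPM after proliferative and 24.2 ± 1.7 after senescent pre-treatment (-1.18 ± 0.10, edgeR adjusted p = 1.89e-10), beside 11.1 ± 1.52 in fresh medium. FOSB (-1.04 ± 0.16, edgeR adjusted p = 5.66e-05) and DUSP1 (-0.57 ± 0.06, edgeR adjusted p = 2.83e-08) also fell. With direct exposure FOS lay at 3.93 to 5.47 CPM in the proliferative and 4.41 to 6.24 in the senescent libraries. Its level was thus higher in both pre-treated groups than in either direct group, a difference that was not tested. The stress gene DDIT4 (-0.78 ± 0.09) of the amino acid response list, the hypoxia target ADM (-0.71 ± 0.13) and the glycolysis gene HK2 (-0.61 ± 0.07) fell. The YAP target ANKRD1 (0.64 ± 0.07, edgeR adjusted p = 2.51e-07), the Wnt inhibitor DKK1 (0.48 ± 0.07) and the amino acid transporter SLC7A5 (0.45 ± 0.05) rose.

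Mitosis genes formed the largest group, since 22 of 33 measured members rose and 0 fell (31 and 0 adjusted over the list alone, camera adjusted p = 3.97e-65), CENPE (0.47 ± 0.08) and AURKA (0.35 ± 0.06) among them. YAP targets such as IGFBP3 (0.39 ± 0.06) followed, and 5 of 16 measured members rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 3.97e-10). Cholesterol genes were higher too, as 6 of 24 measured genes rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.37e-10). Hypoxia was lower, as 0 of 24 measured hypoxia targets rose and 8 fell (0 and 12 adjusted over the list alone, camera adjusted p = 7.83e-15), including SLC2A3 (-0.31 ± 0.04) and PFKFB3 (-0.31 ± 0.06). For the early response 0 of 24 measured immediate early genes rose and 6 fell (2 and 7 adjusted over the list alone, camera adjusted p = 1.41e-08), JUN (-0.37 ± 0.05) among them. No interferon-stimulated gene passed: 0 of 29 measured interferon-stimulated genes rose and 0 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.367).

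The count moved with the fit: 321 genes with a GC and length correction, 39 in a fit of the 6 libraries alone, and 100 without proliferative pre-treatment library 3, 102 without senescent pre-treatment library 1 and 102 without library 2 of that group. With quantile normalization 96 genes were higher and 69 lower. Over the 5575 genes called with the medium present, the slope of the pre-treated on the direct log2 fold changes was 0.065 (0.043 to 0.077 with any 1 library left out, and 0.119 over the 3466 of them with a mean FPKM of at least 5). Of these genes 138 passed after pre-treatment too, 126 of them in the same direction. If every gene were equally likely to be called, 49.6 would pass in both. Genes were not equally likely to be called, as 7.82% passed directly with under 50 counts on average and 47.5% with at least 500. The overlap that chance gives among genes of like depth was not tested.

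**Figure D3:**
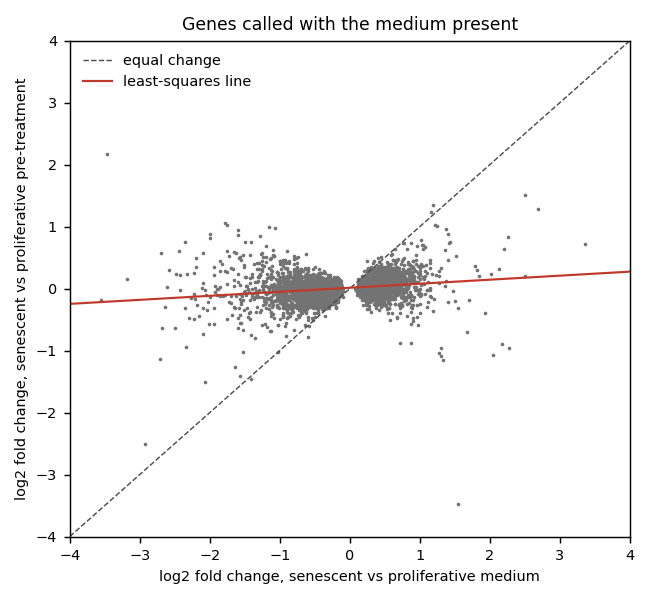
Log2 fold changes of senescent against proliferative medium after pre-treatment (y axis) and with the medium present (x axis), 1 point for each of the 5575 genes called on the x axis. The fitted line has a slope of 0.065 (0.119 over the 3466 genes with a mean FPKM of at least 5), and the dashed line marks equal change.

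Whether the effect of senescent medium differed between pre-treated and directly exposed cells was tested as an interaction, the pre-treated fold change minus the direct one. By this test 1071 genes were higher and 1574 lower. The smallest p values belonged to TGFBI (1.16 ± 0.04, edgeR adjusted p = 1.92e-24), ITGB4 (1.15 ± 0.05, edgeR adjusted p = 7.93e-21) and DUSP1 (-1.45 ± 0.08, edgeR adjusted p = 6.67e-17), then to the matrix protein FN1 (0.58 ± 0.04) and the ubiquitin ligase subunit WSB1 (0.88 ± 0.06). Metal response genes differed, with MT1X (2.12 ± 0.28) and MT1E (1.99 ± 0.16), and 6 of 6 measured members were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 6.43e-15). Antiviral genes such as IFIT2 (1.50 ± 0.12) and OASL (1.63 ± 0.15) differed upward, where 14 of 29 measured interferon-stimulated genes were higher and 1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 7.05e-13). Downward differences included FDPS (-0.83 ± 0.11) and IDI1 (-0.79 ± 0.09), and 0 of 24 measured cholesterol synthesis and uptake genes were higher and 14 lower (0 and 16 adjusted over the list alone, camera adjusted p = 1.27e-14). In replication 0 of 35 measured genes were higher and 20 lower (0 and 25 adjusted over the list alone, camera adjusted p = 3.45e-15). For ribosomes 0 of 40 measured cytosolic ribosomal proteins were higher and 34 lower (1 and 35 adjusted over the list alone, camera adjusted p = 1.96e-38). The numbers higher and lower were 1608 and 976 with library totals, 1009 and 962 with quantile normalization, and 1015 and 2375 with a GC and length correction.

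Each preparation of senescent medium was next set against proliferative medium, to ask whether it still differed. No boiled or fractionated proliferative medium was analysed here, so an effect of the preparation itself was not separated. With boiled medium 1997 genes rose and 1826 fell. The growth response gene EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) stood at 109 ± 3.99 CPM, against 46 ± 3.83 in proliferative and 82.6 ± 3.16 in fresh medium (1.24 ± 0.06, edgeR adjusted p = 6.67e-21). FOS (1.00 ± 0.14) and EGR2 (0.97 ± 0.20) rose with it, and 10 of 24 measured immediate early genes rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 1.2e-06). Hypoxia genes fell, NDRG1 (-1.54 ± 0.04, edgeR adjusted p = 5.25e-32) among them, as 0 of 24 measured hypoxia targets rose and 21 fell (0 and 23 adjusted over the list alone, camera adjusted p = 1.76e-93). Glycolysis went with it, with HK2 (-1.63 ± 0.07): 2 of 19 measured genes rose and 16 fell (2 and 17 adjusted over the list alone, camera adjusted p = 1.72e-40). Chaperones rose, HSPA1B (0.72 ± 0.07) and HSPA8 (0.71 ± 0.04) for example, since 12 of 17 measured heat shock proteins rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.7e-17). In the mitochondrial genome 11 of 13 measured genes rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.07e-25), with MT-CYB (0.68 ± 0.06). For replication 20 of 35 measured genes rose and 2 fell (21 and 3 adjusted over the list alone, camera adjusted p = 2.66e-10), and for mitosis 0 of 33 measured genes rose and 10 fell (0 and 11 adjusted over the list alone, camera adjusted p = 0.00327, adjusted p = 0.243 with an estimated correlation).

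The small fraction gave 2233 rises and 2419 falls against proliferative medium. CA9 fell from 2.83 ± 0.429 to 0.079 ± 0.0953 CPM (-5.12 ± 0.58, edgeR adjusted p = 2.64e-09), beside 0.135 ± 0.18 in fresh medium. NDRG1 fell to 106 ± 0.837 CPM (-4.02 ± 0.04, edgeR adjusted p = 3.14e-47). With ANGPTL4 (-3.85 ± 0.15) and PDK1 (-3.33 ± 0.09), 0 of 24 measured hypoxia targets rose and 24 fell (0 and 24 adjusted over the list alone, camera adjusted p = 6.76e-259). For glycolysis 1 of 19 measured genes rose and 17 fell (1 and 17 adjusted over the list alone, camera adjusted p = 4.84e-172), HK2 (-3.18 ± 0.08) and PGK1 (-2.32 ± 0.03) among them. Mitosis genes fell, in contrast to intact senescent medium: 0 of 33 measured members rose and 31 fell (0 and 31 adjusted over the list alone, camera adjusted p = 1.31e-35), with TTK (-0.83 ± 0.07) and TOP2A (-0.77 ± 0.04). In replication 1 of 35 measured genes rose and 27 fell (1 and 30 adjusted over the list alone, camera adjusted p = 3.5e-13), RRM2 (-1.01 ± 0.08) included. The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) rose from 0.441 ± 0.248 to 3.37 ± 0.808 CPM (2.91 ± 0.51, edgeR adjusted p = 2.61e-05), with 0.514 ± 0.0675 in fresh medium. ANGPTL7 (3.40 ± 0.53, edgeR adjusted p = 2.3e-06), KLF15 (1.74 ± 0.27) and the glycoprotein GPNMB (1.29 ± 0.16) also rose. Metallothioneins were lower, since 0 of 6 measured metallothionein and metal response genes rose and 4 fell (0 and 6 adjusted over the list alone, camera adjusted p = 4.27e-10).

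With the large fraction 2310 genes rose and 1719 fell against proliferative medium. MMP1 reached 46.6 ± 2.55 CPM (2.25 ± 0.10, edgeR adjusted p = 2.67e-20) and INSIG1 39.3 ± 1.54 CPM (1.16 ± 0.08, edgeR adjusted p = 2.47e-14). The growth factor carrier FGFBP1 (2.13 ± 0.24) rose, and OASL (-1.68 ± 0.10) and IFIT2 (-1.65 ± 0.08) fell. Division genes were higher: 29 of 33 measured mitosis genes rose and 0 fell (29 and 0 adjusted over the list alone, camera adjusted p = 2.29e-39), and 28 of 35 measured DNA replication genes rose and 0 fell (29 and 0 adjusted over the list alone, camera adjusted p = 8.69e-31). Lipid synthesis moved with them, as 18 of 24 measured cholesterol synthesis and uptake genes rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 1.48e-43), SQLE (1.09 ± 0.06) among them. Antiviral genes were lower, since 1 of 29 measured interferon-stimulated genes rose and 19 fell (1 and 21 adjusted over the list alone, camera adjusted p = 8.8e-30). AhR targets such as CYP1B1 (0.74 ± 0.08) and AHRR (0.77 ± 0.10) gave 6 of 8 measured members rising and 0 falling (6 and 0 adjusted over the list alone, camera adjusted p = 3.34e-15). Hypoxia genes were split: 3 of 24 measured hypoxia targets rose and 10 fell (4 and 12 adjusted over the list alone, camera adjusted p = 0.00355). With library totals 1628 genes rose and 2424 fell.

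How far each preparation shared the response to intact senescent medium was described by correlation across 19210 genes, which are not independent replicates. Fold changes against proliferative medium correlated with those of senescent medium with r = 0.444 for boiled medium, 0.177 for the small and 0.549 for the large fraction. All of these share the proliferative libraries, which gave a simulated r of 0.5 by themselves, so covariances were compared. The covariance was 0.0864 against a simulated 0.0441 for boiled medium, 0.039 against 0.044 for the small fraction and 0.114 against 0.0437 for the large fraction, and only 3 proliferative libraries set the simulated values. The simulations used 1 dispersion per gene for all groups. The proliferative libraries had the smallest median SD of log2 CPM, 0.0555 beside 0.0681 to 0.0949 in the other groups. The simulated covariances may thus be too high, so the small fraction's value does not show that it shared nothing. Of the genes called in both, 1073 were higher and 800 lower with boiled as with senescent medium, and 237 went opposite ways. For the small fraction 568 were higher and 487 lower in both and 1042 opposite, and for the large fraction 1450 and 943, with 108 opposite. The shared libraries bear on these counts too. In 20 simulations with no effect of any medium 0.05, 0.05 and 0 genes on average were called in both, but these do not give the overlap of 2 real and unrelated responses. The small fraction's r was 0.421 with no filter on low counts, 0.285 in a limma fit with a pseudocount of 0.1 and 0.101 with 1 library of each of 4 groups omitted. After pre-treatment, which shares no library with the direct comparison, r was 0.0736. It was 0.008 with no filter, 0.289 with genes of mean FPKM of at least 5, 0.132 with FPKM as deposited, 0.134 with quantile normalization and 0.033 without proliferative pre-treatment library 1.

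Against intact senescent medium, boiled medium asks what heating changed. As no boiled fresh or proliferative medium was analysed, heating of the medium itself was not separated from heating of senescent cell products. 2157 genes rose and 2822 fell. TGFBI (ENSG00000120708, chromosome 5, 136028895 to 136063818) stood at 1086 ± 15 CPM in senescent and 2858 ± 20.7 in boiled medium (1.40 ± 0.03, edgeR adjusted p = 1.18e-33), above the 2363 ± 25.3 in proliferative and 2252 ± 26 in fresh medium. EGR1 rose (1.45 ± 0.06, edgeR adjusted p = 4.52e-23), as did the transporter ABCC3 (2.00 ± 0.12) and the receptor STRA6 (1.48 ± 0.12). MMP1 fell to 16.4 ± 1.66 CPM (-1.39 ± 0.10, edgeR adjusted p = 3.9e-15), and INSIG1 (-1.38 ± 0.09) and KRT34 (-1.74 ± 0.37) fell. Sterol genes fell as a group, 0 of 24 measured members rose and 21 fell (0 and 22 adjusted over the list alone, camera adjusted p = 1.44e-40). So did mitosis genes, 0 of 33 measured members rose and 31 fell (0 and 31 adjusted over the list alone, camera adjusted p = 6.04e-54), with AURKB (-0.83 ± 0.08). Translation genes were lower than in the senescent libraries, which favoured short genes, since 1 of 40 measured cytosolic ribosomal proteins rose and 36 fell (1 and 38 adjusted over the list alone, camera adjusted p = 1.25e-28). In the mitochondrial genome 12 of 13 measured genes rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 4e-17). Antiviral genes rose, IFIT2 (1.27 ± 0.09) among them, as 13 of 29 measured interferon-stimulated genes rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 2.96e-10). For hypoxia 1 of 24 measured hypoxia targets rose and 18 fell (1 and 19 adjusted over the list alone, camera adjusted p = 5.98e-21). With library totals 2838 rose and 2158 fell.

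The small fraction set against intact senescent medium asks what was lost with the components above 3 kDa. No fractionated fresh or proliferative medium was analysed, so components of the medium itself and the fractionation were not separated from products of senescent cells. Here 3822 genes rose and 4352 fell. CA9 (-4.76 ± 0.60), NDRG1 (-3.58 ± 0.04) and BNIP3 (-2.94 ± 0.05) fell, and 0 of 24 measured hypoxia targets rose and 24 fell (0 and 24 adjusted over the list alone, camera adjusted p = 4.02e-92). Mitosis fell, with TTK (-1.48 ± 0.07) and HMMR (-1.46 ± 0.08), since 0 of 33 measured genes rose and 32 fell (0 and 32 adjusted over the list alone, camera adjusted p = 2.94e-72). DNA replication went the same way: 0 of 35 measured genes rose and 34 fell (0 and 34 adjusted over the list alone, camera adjusted p = 3.11e-39), with RRM2 (-1.50 ± 0.08). MMP1 fell to 12.7 ± 2.11 CPM (-1.76 ± 0.10, edgeR adjusted p = 9.06e-19). GDF15 (2.36 ± 0.48, edgeR adjusted p = 0.000118), GPNMB (2.09 ± 0.17, edgeR adjusted p = 1.87e-13) and MAP1LC3C (2.47 ± 0.20) and SAMD11 (2.22 ± 0.13) rose. Matrix contact genes were lower, with CTGF (-0.98 ± 0.07), as 2 of 16 measured YAP targets rose and 11 fell (3 and 11 adjusted over the list alone, camera adjusted p = 1.64e-08). Ribosomal protein genes fell too, against the same senescent libraries that favoured short genes: 1 of 40 measured cytosolic ribosomal proteins rose and 37 fell (1 and 38 adjusted over the list alone, camera adjusted p = 2.87e-16). With library totals, which moved the median of all genes to 0.11, 5096 rose and 3256 fell.

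The large fraction against intact senescent medium asks what was lost with the components below 3 kDa. As for the small fraction, components of the medium itself and the fractionation were not separated from products of senescent cells. 1563 genes rose and 1921 fell. AhR targets rose, AHRR (1.66 ± 0.10, edgeR adjusted p = 3.82e-16) and CYP1B1 (1.42 ± 0.08, edgeR adjusted p = 1.1e-17) in front, and 5 of 8 measured members rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 3.07e-24). MT1X rose to 23.8 ± 4.7 CPM (1.54 ± 0.20, edgeR adjusted p = 1.57e-05), as did the zinc exporter SLC30A1 (1.40 ± 0.12), and 6 of 6 measured metallothionein and metal response genes rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 9.43e-16). Hypoxia genes were higher, ANGPTL4 (1.15 ± 0.10) and VEGFA (0.66 ± 0.08) among them: 13 of 24 measured hypoxia targets rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.78e-10). TGFBI (1.29 ± 0.03) and ITGB4 (0.93 ± 0.04) rose. INHBE (-1.55 ± 0.27) and TEX19 (-1.54 ± 0.13) fell. Ribosomal protein genes fell, since 0 of 40 measured cytosolic ribosomal proteins rose and 39 fell (1 and 39 adjusted over the list alone, camera adjusted p = 5.09e-72), with RPL9 (-0.89 ± 0.08) and RPL27 (-0.68 ± 0.04). This fall and those with boiled medium and the small fraction share the same 3 senescent libraries. Their deviations correlated with gene length by r = -0.38, -0.38 and -0.26, beside -0.03, 0.045 and -0.076 for the large fraction. Matched random lists were run only for ribosomal proteins between senescent and proliferative medium. Nuclear respiratory genes fell with COX7C (-0.53 ± 0.05), where 0 of 34 measured nuclear oxidative phosphorylation genes rose and 17 fell (2 and 21 adjusted over the list alone, camera adjusted p = 1.85e-08). For mitosis 1 of 33 measured genes rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.16), and for cholesterol 5 of 24 measured genes rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.473, with a median log2 fold change of 0.03, a mean of 0.00 and a test direction of higher). With quantile normalization 1589 rose and 1226 fell, and with a GC and length correction 1243 and 2496.

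The size fractions were compared with each other, which asks how the parts of the medium differ. 3218 genes were higher and 3512 lower with the small fraction. CA9 (-4.59 ± 0.60), ANGPTL4 (-4.48 ± 0.15) and NDRG1 (-3.69 ± 0.04) were lower, and 0 of 24 measured hypoxia targets rose and 24 fell (0 and 24 adjusted over the list alone, camera adjusted p = 5.94e-157). For mitosis 0 of 33 measured genes rose and 32 fell (0 and 32 adjusted over the list alone, camera adjusted p = 4.1e-81), MKI67 (-1.13 ± 0.05) among them. MMP1 was lower (-1.88 ± 0.10, edgeR adjusted p = 7.34e-20), as were the early genes FOS (-1.06 ± 0.14) and EGR3 (-1.17 ± 0.30), since 1 of 24 measured immediate early genes rose and 18 fell (1 and 18 adjusted over the list alone, camera adjusted p = 5.06e-09). GDF15 (3.03 ± 0.50), GPNMB (2.51 ± 0.17) and the antiviral gene IFI44L (1.81 ± 0.11) were higher, and 19 of 29 measured interferon-stimulated genes rose and 3 fell (19 and 3 adjusted over the list alone, camera adjusted p = 6.4e-10). Metallothioneins were lower: 0 of 6 measured metallothionein and metal response genes rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 6.15e-06). With library totals the counts were 4107 and 2689.

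Lists for other cells and for RNA quality were also called in some comparisons. Against intact senescent medium, fibroblast markers were higher with boiled medium, as 3 of 6 measured markers rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.00533), a call lost in limma fits of FPKM (adjusted p = 0.106 to 0.153). With the small fraction 3 of 6 measured markers rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0276, adjusted p = 0.107 with an estimated correlation), lost with no filter on low counts (adjusted p = 0.145), with a GC and length correction (0.115) and without senescent library 3 (0.0554). Of the measured fibroblast markers 1 is also in the matrix list. Histone transcripts, most of which lack a polyA tail, were higher with the large fraction than with intact senescent medium, as 5 of 14 measured genes rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00123), lost with genes of mean FPKM of at least 5 (adjusted p = 0.077). After pre-treatment 0 of 14 measured histone genes rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.0397, adjusted p = 0.094 with an estimated correlation). That call was lost without proliferative pre-treatment library 1 (adjusted p = 0.23) or 2 (0.0595), without senescent pre-treatment library 1 (0.0602) or 3 (0.362), with genes of mean FPKM of at least 5 (0.182), with a GC and length correction (0.098) and with 4 libraries omitted (0.7). In the interaction 4 of 14 measured histone genes were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.00302). Against proliferative medium 1 of 5 measured nuclear and non-coding RNAs rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.00327, with a median log2 fold change of -0.37, a mean of 0.22 and a test direction of lower) with boiled medium, and 1 of 5 measured such RNAs rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.000679, with a median log2 fold change of -0.39, a mean of 0.31 and a test direction of lower) with the large fraction.

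**Figure D4:**
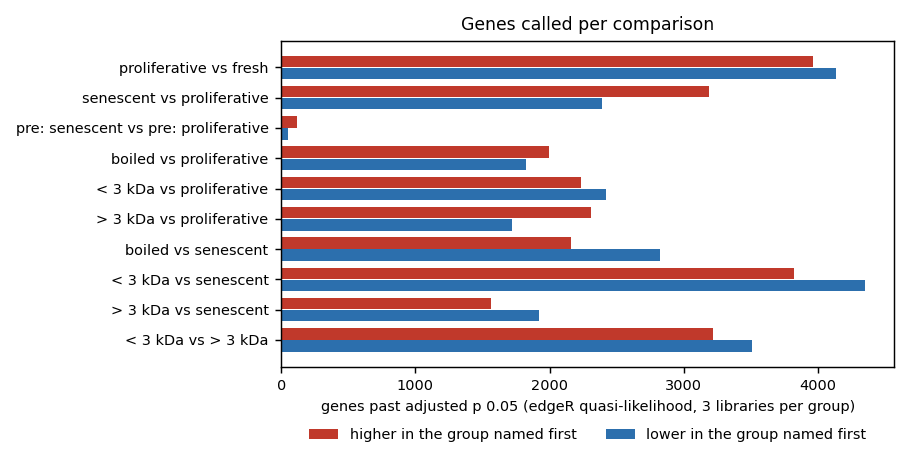
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood, 3 libraries per group) that were higher or lower in the first-named group, for 10 comparisons. The bars run from 51 genes lower after pre-treatment to 4352 lower with the small fraction than with intact senescent medium.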

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

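The test of near-identical gene copies, the slope over genes with a mean FPKM of at least 5, the spread within groups, the 2 tests of ribosomal protein transcripts by the length of coding transcripts and the breakdown of the splits of 12 libraries were chosen only after the results were seen. The effect of senescent against proliferative medium differed between pre-treated and directly exposed cells by the interaction test for 2645 genes, counted over 12 libraries. The smallest p values, with the pre-treated minus the direct log2 fold change, belonged to TGFBI (1.16 ± 0.04), ITGB4 (1.15 ± 0.05), DUSP1 (-1.45 ± 0.08), FN1 (0.58 ± 0.04) and WSB1 (0.88 ± 0.06). Of 100 splits of these libraries, the real one included, 7 gave as many genes, so by this count chance is not excluded, and the highest other gave 5094. The 6 others had 5 or 6 of the 6 pre-treated libraries on one side of the contrast, as 10 of the 100 splits did. The highest among the rest was 808. This points to a structure of the samples, the difference between pre-treated and directly exposed cells.

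For each comparison of 3 against 3 libraries, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 8104 for proliferative against fresh, 5575 for senescent against proliferative and 171 for the pre-treated pair. Against proliferative medium they were 3823 for boiled medium, 4652 for the small and 4029 for the large fraction. Boiled against senescent medium gave 4979, the large fraction against senescent medium 3484 and the small against the large fraction 6730. The highest other was 0 in each of these, and 128 beside 8174 for the small fraction against senescent medium. Every other split mixed libraries of the 2 groups, which adds the difference between the groups to the spread. Low counts there therefore do not measure chance.

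Few genes changed after pre-treatment, 171 against 5575 with the medium present. A larger spread between the pre-treated libraries would leave the slope of the pre-treated on the direct log2 fold changes near 1, but over the 5575 genes it was 0.065 (0.043 to 0.077 with any 1 library left out, and 0.119 over 3466 genes with a mean FPKM of at least 5). The median SD of log2 CPM within groups was 0.0942 and 0.0869 for the pre-treated and 0.0555 and 0.0816 for the direct groups, a larger spread, which leaves the slope unbiased. With a correction for GC content and gene length the pre-treated pair gave 5.06% as many genes as the direct one, which argues against these trends as the whole cause. A smaller effect after pre-treatment may thus be biological, as a hypothesis found and tested on the same data, and what followed the pre-treatment is not given in the sources used here, so loss with time and absence of the medium stay open.

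Ribosomal protein transcripts were higher with senescent than with proliferative medium, with a median log2 fold change of 0.36. Corrected for GC content and the gene length in the table, the median was 0.35 (0.34 to 0.35 with any 1 of 6 libraries left out) and 35 of 40 members rose, and corrected for GC content and the length of coding transcripts it was 0.33 (0.32 to 0.36), which argues against these trends as the whole cause. The list stood at percentile 100, also with any 1 of the 6 libraries left out, of 10000 random lists of protein-coding genes matched in the length of coding transcripts, GC content and expression, whose highest median was 0.22 and typical median 0.09. The medians of the matched genes and the list were 722 and 734 bases, 50.9% and 51.4% GC and a log2 CPM of 9.41 and 9.66. Matched genes as a class thus rose by less than the list (0.09 against 0.36). The random lists took their members singly from 153 distinct genes, whereas ribosomal protein genes may vary together. The percentile therefore cannot settle how much of the rise short abundant transcripts as a class account for. Reads shared with pseudogenes were not tested for this list and stay open, as does an effect of the medium on translation genes.

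In 5 pairs of near-identical genes a member changed by over 2 on the log2 scale, such as MAGED4B (-3.47) and SERF1B (2.69) with senescent against proliferative medium, EIF3CL (-3.10) and BOLA2B (-4.40) with the small fraction against senescent medium, and XAGE1A (3.50) between the fractions. Reads shared between the copies could give such changes, and then the summed counts of a pair would change little, as for MAGED4 with MAGED4B (-0.34) and EIF3C with EIF3CL (-0.10) in these comparisons. The sums of 4 pairs changed by over 1 in some comparison, but in only 2 of them (SERF1A with SERF1B, 1.86, and MAGED4 with MAGED4B, -2.21 for the small fraction against proliferative medium) without overlap between the libraries. By chance 10% of unchanged pairs would show no overlap in a single comparison, and more would over the several comparisons searched. The requirement of no overlap was added after the sums were seen. Several calls rest on single libraries: without senescent library 1, BOLA2B stood at -0.16 (adjusted p = 0.952) and EIF3CL at -1.70 (adjusted p = 0.327), SERF1B at 1.84 without senescent library 2 (adjusted p = 0.0827) and XAGE1A at -0.24 without small fraction library 1 (adjusted p = 0.901). Shared reads and a change of expression cannot be told apart for these pairs, because few pairs exist and their counts vary between libraries.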

How the results depend on the processing

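The fits with DESeq2 size factors, library totals, no robust dispersion, scaled FPKM with a pseudocount of 1, a GC and length correction and 4 libraries omitted were chosen only after the results were seen. Of 226 counts of genes over 11 contrasts and their alternatives, 215 lay within 1.5 times the reported count, and of 226 counts of called lists 224 did. Of 2749 values of 203 named genes under the alternatives that keep their replicates, 2731 kept their direction and their side of the threshold, 17 kept the direction only and 1 reversed. With single libraries left out, 1271 of 1284 kept both, 12 kept the direction only and 1 reversed. The named genes were mainly taken because their calls held with any 1 library left out, so this share was largely set by that choice. The values under the other alternatives cover the same chosen genes. For 214 called lists, 2732 of 2977 values kept both, and with single libraries left out 1355 of 1410 did. With an estimated correlation 170 of the 214 kept both and 44 kept the direction only. The rest kept only the direction of the test, except that for senescence-associated genes it reversed with quantile normalization, while their mean stayed negative, at -0.04 for boiled against senescent medium (adjusted p = 0.837) and -0.06 in the interaction (adjusted p = 0.718), and the cause was not tested. The mean log2 fold change of a called list changed sign in 15 of the 2977 and 7 of the 1410 values.

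With only genes of a mean FPKM of at least 5, 7602 were tested, and the number called was 4528 for proliferative against fresh, 3526 for senescent against proliferative, 3066 for the small fraction against proliferative, 3198 for boiled against senescent, 4504 for the small fraction against senescent and 3815 between the fractions. By construction fewer genes were tested there. The fractions then gave 14 called lists rather than 23. Lists left with under 5 measured genes gave no value at that filter. With an estimated correlation the small fraction against senescent medium gave 13 called lists rather than 21.

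After pre-treatment the 171 genes became 321 with the GC and length correction and 39 with only the libraries compared. That last fit has fewer libraries to estimate the spread, and it does not pool the spread over all groups. The median SD of log2 CPM was 0.0942 after proliferative and 0.0869 after senescent pre-treatment, within 0.0555 to 0.0949 over all groups. With the pooled spread the p values of the 171 genes may thus be too small. With 1 library left out the count ran from 100 to 149, with 100 without proliferative pre-treatment library 3 and 102 without senescent pre-treatment library 1 or library 2. The cause was not tested for the correction, for the libraries compared or for single libraries. DESeq2 gave 227.

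The correlation with the response to senescent medium was 0.444 for boiled medium, and 0.510 at a mean FPKM of at least 5, 0.353 with 4 libraries omitted and 0.353 to 0.501 with 1 left out. For the small fraction it was 0.177, and 0.421 with no filter, 0.285 with a pseudocount of 0.1, 0.231 with quantile normalization, 0.101 with 4 libraries omitted and 0.124 (without senescent library 3) to 0.253 with 1 left out. For the large fraction it was 0.549, and 0.471 with no filter, 0.637 at a mean FPKM of at least 5, 0.453 with 4 libraries omitted and 0.453 to 0.594 with 1 left out. For the pre-treated pair it was 0.0736, and 0.008 with no filter, 0.289 at a mean FPKM of at least 5, 0.132 with FPKM as deposited and with scaled FPKM and a pseudocount of 1, 0.134 with quantile normalization, and 0.033 (without proliferative pre-treatment library 1) to 0.082 with 1 left out. The cause was not tested.

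XAGE1A, higher with the small than with the large fraction (3.50), stood at -0.24 with 4 libraries omitted and ran from -0.24 to 4.95 with 1 library left out, lowest without small fraction library 1, which the 4 include. The cause was not tested. Other calls were lost for MAGED4B, SERF1B, BOLA2B and EIF3CL, whose copies are near-identical. A block for the replicate number kept 414 of 417 calls of named genes and lists, and gave 5515 genes for senescent against proliferative medium. Libraries with equal numbers were not alike beyond their groups: the median correlation of their residuals was -0.064, -0.003 and -0.083 for the 3 numbers (-0.43 to 0.61), and 8 of 24 libraries correlated best with one of their own number. Depth limits the precision for weakly expressed genes: between senescent and proliferative medium the median standard error of the log2 fold change was 0.46 for 6212 genes with under 50 counts on average, where counting alone gives 0.32, and 0.064 for 6553 genes with at least 500 counts, where counting gives 0.035. This table was made after the results were seen.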

Other observations

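Every comparison here was planned, while the groupings of lists across preparations were chosen after the results were seen. Genes of the aryl hydrocarbon receptor response, which follow small aromatic ligands, were higher with boiled than with intact senescent medium: 5 of 8 measured AhR targets rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 6.96e-08), with CYP1B1 (1.32 ± 0.08) and AHRR (1.30 ± 0.11). Against proliferative medium, 5 of 8 measured AhR targets rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 1.36e-05) with boiled medium, NQO1 (0.53 ± 0.05) among them. More antioxidant genes of the NRF2 response rose than fell against proliferative medium with each preparation: 7 of 22 measured NRF2 targets rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00251) with boiled medium, 11 of 22 measured NRF2 targets rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000207) with the small fraction, TKT (0.64 ± 0.04) among them, and 12 of 22 measured NRF2 targets rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 9.88e-05) with the large fraction. With intact senescent medium more NRF2 targets rose than fell too, but the list was not called. Folding genes of the endoplasmic reticulum were higher with boiled medium, since 10 of 19 measured unfolded protein response genes rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 9.32e-09), HSPA5 (0.45 ± 0.03) and PDIA4 (0.41 ± 0.04) included.

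Matrix and adhesion genes rose more often than they fell without the components below 3 kDa, against intact senescent medium, since 12 of 26 measured extracellular matrix and integrin genes rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 2.34e-09), with FN1 (0.84 ± 0.03) and ITGB8 (0.58 ± 0.05). In boiled medium 13 of 26 measured such genes rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 1.74e-05), with ITGB4 (1.12 ± 0.04) and FN1 (0.85 ± 0.03) higher and COL12A1 (-1.36 ± 0.05) and LAMB3 (-1.01 ± 0.09) lower, and the fibroblast marker list was called higher there too (3 of 6 measured markers rose and 1 fell). The epithelial list was split with the large fraction against proliferative medium: 4 of 14 measured epithelial genes rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.00355), with changes from -0.96 to 1.22, KRT7 (0.57 ± 0.04) and KRT18 (0.51 ± 0.04) rising. LXR targets, genes that answer sterols, were higher with the small than with the large fraction: 5 of 8 measured LXR targets rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.000489), APOE (0.87 ± 0.05) and MYLIP (0.75 ± 0.08) included.

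Genes of the respiratory chain split by genome. With the large fraction against intact senescent medium, 10 of 13 measured mitochondrially encoded genes rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.54e-07, adjusted p = 0.0977 with an estimated correlation), MT-ND5 (0.45 ± 0.04) among them, while 0 of 34 measured nuclear ones rose and 17 fell (2 and 21 adjusted over the list alone, camera adjusted p = 1.85e-08). Mitochondrially encoded transcripts made up 4.09% to 6.85% of a library's counts over the 24 libraries. They made up 4.09%, 4.12% and 4.79% in the senescent libraries and 5.22%, 5.4% and 5.02% in those of the large fraction. The senescent libraries favoured short genes (r = -0.38, -0.38 and -0.26 with gene length), beside -0.03, 0.045 and -0.076 for the large fraction. This split therefore rests on libraries that differed in that trend too. GPNMB, a glycoprotein of lysosomes, stood at 21.8 ± 2.59 CPM with the small fraction and at 2.51 ± 0.5, 8.91 ± 1.83 and 5.11 ± 0.268 in fresh, proliferative and senescent medium (mean ± SD, 3 libraries each). No hypothesis beyond those of the first part was tested.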
